A study of Mus musculus with 8 samples.

How the data were processed

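Single-cell 3' RNA libraries (10x Genomics, v3.1 chemistry) were made from hematopoietic progenitors of femur and tibia marrow of tumor-bearing FVB/NJ mice, separated with magnetic beads after red cell lysis, per the labels. There were 8 libraries in 4 groups of 2 (vehicle, GC, VXGC and VX, where VX is matched to the Casp1 inhibitor arm of the protocol), each loaded to recover 10000 cells per the labels. The authors deposited 1 matrix of raw UMI counts per library, with 32285 genes, and the counts came from Cell Ranger 7.1.0 with the mouse genome build mm10, per the submitters' processing notes. The deposited matrices held 300910 barcodes in all, each with at least 500 UMIs, far above the loading target. How barcodes were chosen for the matrices, and whether replicates were separate animals or pools, is not given in the sources used here. A cell annotation by the authors was not used here. The lowest barcode total of 500 UMIs leaves room for droplets with background RNA, so the filters below decide which barcodes count as cells.

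Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Of the barcodes, 18.3% (GC replicate 2) to 49.4% (VX replicate 2) had under 1000 UMIs, so the UMI minimum removed an unequal part of the libraries. Doublets were scored per library by the Scrublet method, which compares each cell with simulated pairs, and the highest scores were removed at 0.8% per 1000 barcodes, up to 20%. The removal is by rank and takes a share set in advance. Counts were scaled to 10000 UMIs per cell. Clustering used 5000 cells per library, 2000 variable genes, 30 principal components, 20 neighbours and the Leiden algorithm at resolution 1.0, and the other cells took the cluster of their 15 nearest clustered cells. Clusters were named from 18 panels of marker genes fixed before the data were examined, and 4 of 21 clusters stayed unnamed. The tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and Matplotlib 3.10.9.

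Cells are not replicates, so raw counts were summed per library and cell class, and the sums were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr). All 8 libraries entered 1 fit per class, with group as the only term and 4 residual degrees of freedom. The classes for these tests were fixed beforehand as the stem-like, GMP-like, neutrophil-like, monocyte-like and erythroid-like, and a class entered if every library had at least 50 cells of it, which 4 of the 5 met. Other classes with as many cells were not tested in these comparisons. P-values were adjusted by the Benjamini-Hochberg method within class and comparison, with a threshold of 0.05. The comparisons were GC against vehicle, VXGC against GC, VX against vehicle, and the interaction, which is VXGC against GC minus VX against vehicle. Shares of classes were tested with edgeR on cell counts, with the total cells of the library as offset, and for each drug with an exact two-sided permutation test of mean log2 shares in 4 against 4 libraries, adjusted over 5 classes and 2 drugs. The spread of a pair of libraries is poorly known, and a group mean ± SD rests on n = 2.

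In addition, 19 gene lists were tested per class: primary granule, late granule (secondary and tertiary granule and S100 genes), granulopoiesis regulators, interferon response, NF-kB response, inflammasome and IL-1 family, p53 targets, S phase, G2 and M phase, stem cell maintenance, heme (with hemoglobin), lymphoid priming, MHC class II, monocyte and dendritic cell program, integrated stress (with ER stress), immediate early response, glycolysis and hypoxia, cholesterol synthesis, and sex-linked genes. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry alongside, for lists with at least 3 measured genes. Members were also counted past the gene test over all genes and adjusted over the list alone. The sex-linked list served as a check of the samples, and several lists share genes with the marker panels. The named genes were, per class and comparison, up to 3 higher and 3 lower genes with the largest fold among those past the threshold, with mean log2 CPM of at least 5 and separate groups. Unnamed gene models, mitochondrial and ribosomal protein genes were left out of that rule. List members past the threshold over all genes, and Casp1, Il1b, Il18 and Gsdmd whatever their p, were added.

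The design, tests, lists and the rule for named genes were fixed before the data were examined, and so were most alternatives: RLE scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), doublets kept, only the 2 groups compared, TMM over classes, a second clustering at resolution 1.5, shares on a linear scale, an estimated correlation, and each library left out in turn. Chosen after the data were seen were barcodes from 500 UMIs and 250 genes, cells with under 30 UMIs of 13 erythroid genes per 10000, the shares without cluster 8, the erythroid-like class without clusters 2 and 5, the permutation tests over all 13 classes, and the gene tests of 4 libraries with a drug against 4 without it. For the permutation tests of drug effects, the stricter filter, doublets kept and the second clustering were also not planned beforehand. In a fit without 1 library, the lone library of its group is assumed to vary like the other groups.

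The gene test was checked on simulated counts with 200 changed genes. For GC against vehicle, 2-fold changes were recovered at 62% in the stem-like class (12352 genes), 64% in the GMP-like (10306), 53% in the monocyte-like (8903) and 76% in the erythroid-like class (12903), and 4-fold changes at 90%, 96%, 92% and 96%. For VXGC against GC the shares were 59%, 60%, 44% and 67%, and 94%, 94%, 86% and 90%. For VX against vehicle they were 55%, 47%, 45% and 63%, and 94%, 91%, 90% and 88%. For the interaction they were 29%, 18%, 11% and 61%, and 81%, 78%, 66% and 81%. False calls numbered 2 to 8 per test. The simulated libraries shared the same mean and spread for each unchanged gene, so none stood apart from the rest. In the real data single libraries did stand apart, so these recovery shares may be too high for them. A lack of calls therefore does not show that large changes are absent. Gene positions come from the GENCODE vM21 annotation of GRCm38, the assembly of mm10.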

Results

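Gene expression was measured in single cells of hematopoietic progenitor preparations from the bone marrow of tumor-bearing mice. The title of the series places the work in the question of how an inflammatory caspase-1 program in a tumor alters blood formation in the marrow and drives neutrophils. The mice were of the inbred strain FVB/NJ and 12 to 13 weeks old, and received 2 cycles of treatment. There were 4 groups of 2 libraries each: vehicle, the chemotherapy that the labels call GC, VX, and both together (VXGC). The titles do not say what VX is; it is read here as the Casp1 inhibitor because the protocol lists such an inhibitor among its treatment arms. The labels number the replicates 1 and 2 but do not say whether they were separate animals, so every p-value here measures only the spread between these samples, which may be technical. The libraries held 57688302 (VX replicate 2) to 79363582 (GC replicate 1) UMIs, that is, counted mRNA molecules. They held 27397 to 42354 barcodes, against a loading target of 10000 cells. Filtering and doublet removal left 16768 to 24210 cells per library and 166525 in all. The median per kept cell ran from 1368 UMIs in VX replicate 2 to 2093 in GC replicate 2.

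Clustering gave 21 clusters, of which 17 were named from marker genes and joined into 13 classes. The erythroid-like class was the largest, at 22.9% to 59.5% of cells per library, followed by a stem-like class of stem and multipotent progenitors at 8.96% to 16.3%. Early lymphoid-like cells made up 6.51% to 11.7%, granulocyte-monocyte progenitor-like (GMP-like) cells 1.96% to 8.70%, and monocyte-like cells 1.09% to 3.23%. The top 10 genes of the early lymphoid-like cluster held 2 markers of its own panel and 2 of the stem-like panel. The erythroid name is weak for clusters 2 and 5, of 19432 and 13537 cells: 1 of 17 erythroid markers in each exceeded 1.5 times the median of the other clusters, none was among the top 10 genes, and in cluster 2 the erythroid panel scored below the eosinophil panel. Their names rest on 7 and 8 markers that stood above every named cluster outside the class. Among these was Car1, a carbonic anhydrase of red cell precursors, at 2151 and 2016 CPM against at most 1352. The rest of the 17 did not, such as Slc4a1 at 236.5 and 459.5 CPM against 627.7. By the same count the unnamed clusters 17 and 8 held 11 and 10 markers, so it does not settle the names. Without clusters 2 and 5, the erythroid-like class was 12.8% to 40.2% of cells per library. In cluster 17, which stayed unnamed, the erythroid panel scored highest, but the leading genes included Gata3 and Bcl11b, regulators of T cell development. Genes were tested in the stem-like, GMP-like, monocyte-like and erythroid-like classes, which held at least 183 cells in every library. The neutrophil-like class had only 43 cells in GC replicate 2 and was compared by its share alone. In the replicate pairs, counts differed far beyond sampling noise, with a chi-square per degree of freedom of 15.34 in VXGC, 17.58 in VX, 27.12 in vehicle and 98.6 in GC. GC replicate 2 also stood apart in erythroid transcripts. Of its stem-like cells, 74.0% held few of them, against 9.11% to 26.8% in the 7 other libraries. Its erythroid-like share of 59.5% was nonetheless the highest. Hbb-bs, a hemoglobin gene, reached 18800 CPM in a named cluster outside the erythroid-like class, against 6866 CPM in erythroid cluster 2. Whether stray erythroid RNA in the other libraries or its lack in GC replicate 2 is the unusual side was not tested.

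The first comparison asked how GC chemotherapy changed the make-up of the progenitor pool. Neutrophil-like cells made up 0.356% ± 0.169 (SD, n = 2) of cells after GC and 4.84% ± 6.21 after vehicle, where the libraries stood at 9.22% and 0.448%. B-lineage-like cells made up 0.535% ± 0.608 after GC and 3.78% ± 3.45 after vehicle. Erythroid-like cells made up 48.6% ± 15.5 and 37.3% ± 10.7, GMP-like cells 6.22% ± 3.51 and 3.88% ± 0.117, stem-like cells 12.6% ± 5.17 and 12.3% ± 0.414, and monocyte-like cells 2.55% ± 0.633 and 2.51% ± 1.02. In edgeR's quasi-likelihood test on cell counts, 0 of 13 classes passed, with 2 at an unadjusted p under 0.05. These 2 were the neutrophil-like class (log2 ratio −3.76, SE 1.30, adjusted p = 0.244) and the B-lineage-like class (log2 ratio −2.82, SE 1.12, adjusted p = 0.244). The vehicle libraries decide the size: without vehicle replicate 2, the log2 ratios were −4.69 (adjusted p = 7.8e-05) and −3.53 (adjusted p = 0.0014) and 3 classes passed, and without vehicle replicate 1 the neutrophil-like ratio was −0.33. With the replicate number as a block, the B-lineage-like class passed edgeR's test. All shares are of cells left after immunomagnetic isolation and filtering, and say nothing of cell numbers in the marrow.

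**Figure D1:**
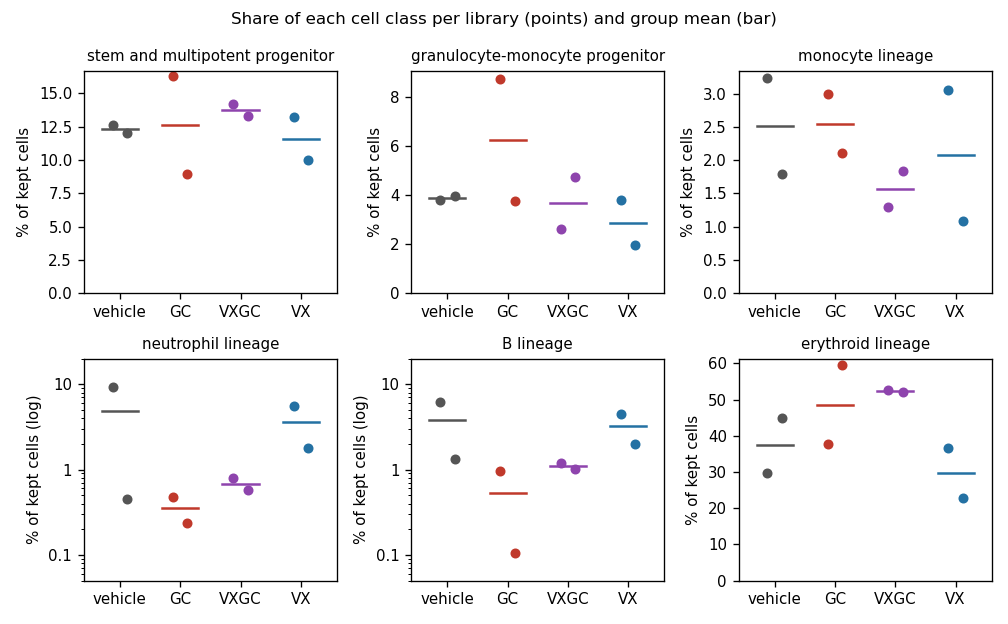
Share of all kept cells (percent) in 6 cell classes for the 4 groups, with each library as a point and the group mean as a bar; the neutrophil and B lineage axes are logarithmic. The vehicle libraries lie at 9.22% and 0.448% for the neutrophil class, and the GC libraries at 0.476% and 0.236%.

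Pooling the libraries by drug gave groups of 4. Erythroid-like cells made up 50.5% ± 9.22 (SD, n = 4) of the libraries given GC, alone or with VX, and 33.6% ± 9.43 of those not given it. The difference of mean log2 shares was 0.61 (exact two-sided permutation test over 70 arrangements, p = 0.0571, adjusted p = 0.571). It was 0.35 with the strict cell filter (exact permutation p = 0.171) and 0.42 without cluster 8, which held 41.3% of VX replicate 2 (exact permutation p = 0.0857). Neutrophil-like cells made up 0.521% ± 0.230 with GC and 4.24% ± 3.96 without it (difference −2.40, exact permutation p = 0.114). For GC, the differences were 0.47 for GMP-like, 0.12 for stem-like and −0.09 for monocyte-like cells. For VX, they were −0.60 for GMP-like, −0.55 for monocyte-like, 0.82 for neutrophil-like, 0.05 for stem-like and −0.09 for erythroid-like cells. Without cluster 8, the VX differences were −0.41 for GMP-like, −0.36 for monocyte-like, 1.005 for neutrophil-like, 0.23 for stem-like and 0.09 for erythroid-like cells. The VX value was −0.14 for GMP-like cells with the second clustering and −0.13 for monocyte-like cells with the strict filter. For monocyte-like cells it was larger with the second clustering, at −0.81 (exact permutation p = 0.0571), and with barcodes from 500 UMIs, at −0.74 (exact permutation p = 0.114). None of the 10 tests in the main setting passed. Apart from the erythroid-like and neutrophil-like tests of GC, their exact permutation p was 0.229 or above, where the design can reach 0.0286.

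Within cell classes, edgeR called 4 genes of erythroid-like cells for GC against vehicle with all libraries. Cpd, which encodes the membrane-bound carboxypeptidase D, rose from 27.2 ± 5.76 to 127.0 ± 32.7 CPM (SD, n = 2 per group; log2 fold change 2.23, SE 0.21, adjusted p = 0.0184). Tjp1, which encodes the tight junction scaffold ZO-1, rose from 2.68 ± 0.311 to 19.4 ± 5.06 CPM (log2 fold change 2.85, SE 0.27, adjusted p = 0.0184). Prss50, a gene of the serine protease family, fell from 11.1 ± 0.934 to 2.62 ± 0.698 CPM (log2 fold change −2.10, SE 0.22, adjusted p = 0.0264). Gm11837, annotated as an antisense transcript, fell from 39.6 ± 1.01 to 20.5 ± 1.72 CPM (log2 fold change −0.95, SE 0.10, adjusted p = 0.0264). Only Cpd met the rule for named genes; the other 3 complete the count of 4 and were chosen after their values were seen. In the mm10 build, Cpd (ENSMUSG00000020841) lies on chromosome 11 from 76778424 to 76847018 on the minus strand, Tjp1 (ENSMUSG00000030516) on chromosome 7 from 65296165 to 65527781 on the minus strand, Prss50 (ENSMUSG00000048752) on chromosome 9 from 110857967 to 110864629 on the plus strand, and Gm11837 (ENSMUSG00000086587) on chromosome 4 from 14929908 to 14953030 on the plus strand. Whether reads of an overlapping gene contribute to the value of Gm11837 was not checked.

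**Figure D2:**
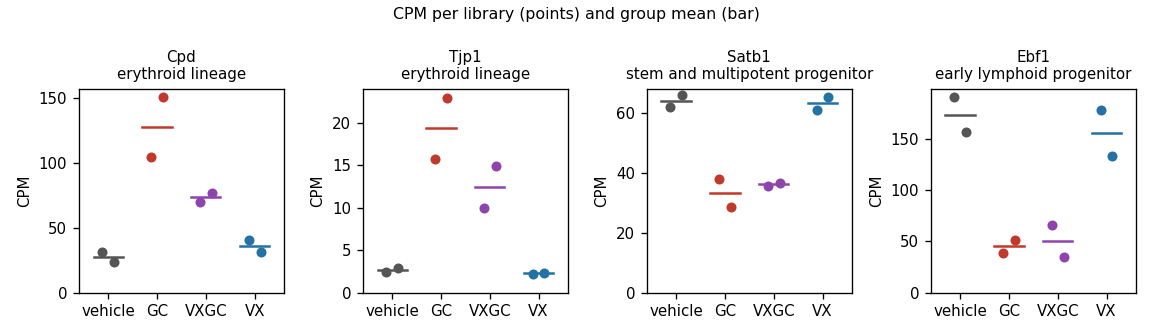
CPM of Cpd and Tjp1 in the erythroid-like class, Satb1 in the stem-like class and Ebf1 in the early lymphoid-like class. Each library is a point and the group mean a bar. Counts were scaled to the TMM-adjusted total of the class in each library. Cpd lies at 103.9 and 150.1 in the GC libraries and at 31.3 and 23.1 in the vehicle libraries.

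The 4 erythroid genes came from 12903 tested, of which 1256 had an unadjusted p under 0.05, and DESeq2 called 97. Without clusters 2 and 5 the count was 5, and Prss50 (Prss50, GC vs vehicle: erythroid lineage) was not called (adjusted p = 0.0639). The edgeR counts were 0 in the stem-like, GMP-like and monocyte-like classes, with 537, 331 and 256 genes at an unadjusted p under 0.05, where DESeq2 called 3, 0 and 0. The counts hang on single libraries. The erythroid count was 1637 without GC replicate 1, 428 without GC replicate 2, 6 without vehicle replicate 2, 2 without VXGC replicate 1, 1 without VXGC replicate 2, and 0 without vehicle replicate 1, VX replicate 1 or VX replicate 2. All 4 genes were among those called when GC replicate 1 or GC replicate 2 was left out, 0 of the 4 were among the 6 without vehicle replicate 2, and of the 4 only Tjp1 was called when either VXGC replicate was left out. The stem-like, GMP-like and monocyte-like counts were 2126, 738 and 337 without GC replicate 1, 54, 137 and 18 without GC replicate 2, and 0, 2 and 7 without vehicle replicate 2. The erythroid-like class spans 5 clusters, and cluster 5 held 6.87% of it in GC replicate 2, against 18.9% to 27.2% elsewhere.

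Among the gene groups, late granule genes of neutrophils stood lower after GC in GMP-like cells, with a median log2 fold change of −1.57 over 12 measured members, all negative. Chil3, a chitinase-like protein of immature neutrophils, stood at 5.21 ± 4.38 CPM after GC and 24.5 ± 14.6 after vehicle (log2 fold change −1.97, SE 0.46). Fcnb, a ficolin of neutrophil granules, stood at 18.6 ± 11.3 and 50.02 ± 10.5 CPM (−1.29, SE 0.30), and Camp, the cathelicidin precursor, at 43.3 ± 44.8 and 260.5 ± 163.0 CPM (−2.47, SE 0.59). The values of Chil3, Fcnb and Camp were −3.48, −2.22 and −4.47 without GC replicate 1, and those of Chil3 and Camp −1.19 and −1.63 without vehicle replicate 1. The list was called down by limma's camera (adjusted p = 1.3e-11), which compares it with all other genes, and not with fry (adjusted p = 0.363). The call was lost with an estimated correlation (adjusted p = 0.341 with an estimated correlation). Adjusted over the list alone, 8 members were lower, and 0 passed over all genes. The share of neutrophil-like cells moved with these genes: in GMP-like cells, 6 late granule genes summed to 2020 and 822 CPM in the vehicle libraries, 648 and 283 in GC, 525 and 905 in VXGC, and 2767 and 2237 in VX. In monocyte-like cells the list was also called down (10 members, median −2.39, adjusted p = 1.0e-04, adjusted p = 0.419 with an estimated correlation), but without vehicle replicate 1 it pointed up (adjusted p = 0.142). There Camp and Ngp, both granule proteins, moved from −2.89 and −3.63 to 0.47 and 0.71 without vehicle replicate 1.

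**Figure D3:**
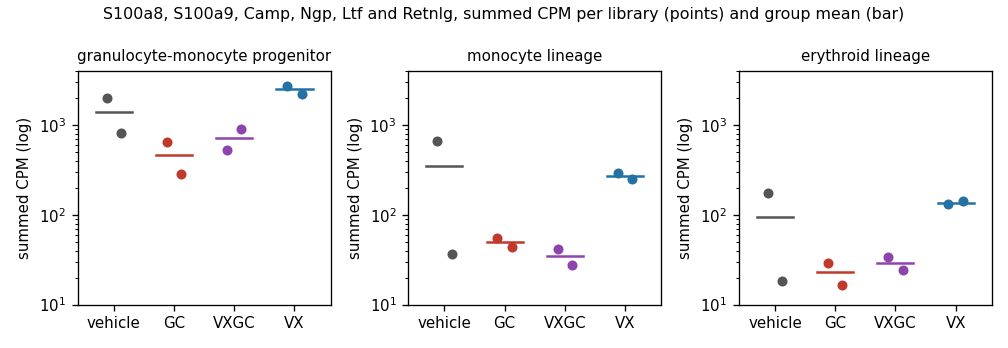
Summed CPM (log axis) of S100a8, S100a9, Camp, Ngp, Ltf and Retnlg per library (points) and group mean (bars) in the GMP-like, monocyte-like and erythroid-like classes. Here counts were scaled to the class total in each library without TMM. In the GMP-like class the sum is 2020 and 822 in vehicle, 648 and 283 in GC, and 2767 and 2237 in VX.

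Lymphoid priming genes stood lower after GC in stem-like cells, with a median log2 fold change of −0.74 over 10 measured members. Satb1, a chromatin organizer of lymphoid commitment, stood at 33.2 ± 6.72 CPM after GC and 63.9 ± 2.95 after vehicle (−0.92, SE 0.16, adjusted p = 0.0021 over the list alone). Dntt, the terminal transferase of antigen receptor rearrangement, stood at 26.6 ± 1.97 and 47.0 ± 4.88 CPM (−0.81, SE 0.19), and Ebf1, a transcription factor of early B cells, at 3.16 ± 1.31 and 18.6 ± 16.4 CPM (−2.44, SE 0.63). The Ebf1 value ran from −3.89 in cells low in erythroid RNA to −1.02 without vehicle replicate 1. The share of B-lineage-like cells moved with it, at 6.22% and 1.34% in vehicle and 0.965% and 0.104% in GC. Camera called the list down (adjusted p = 1.5e-05, adjusted p = 0.128 with an estimated correlation), and fry gave an adjusted p of 0.0437. Adjusted over the list alone, these 3 members passed and 0 passed over all genes. In monocyte-like cells, primary granule genes stood higher after GC (10 members, median 0.52, adjusted p = 1.0e-04, adjusted p = 0.419 with an estimated correlation). Adjusted over the list alone, 2 were higher: Ms4a3, a marker of granulocyte-monocyte progenitors, at 50.7 ± 18.8 against 19.2 ± 0.370 CPM, and Mpo, the myeloperoxidase, at 546.2 ± 233.4 against 315.9 ± 44.4 CPM. That call was lost without vehicle replicate 2 (adjusted p = 0.0693) and without GC replicate 2 (adjusted p = 0.453).

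In erythroid-like cells, genes of the integrated stress response and of glycolysis both stood higher after GC, each with a median log2 fold change of 0.38 over 13 members. Among the stress genes, Psat1 and Phgdh, enzymes of serine synthesis, stood at 53.2 ± 3.09 against 32.4 ± 1.54 CPM (0.71, SE 0.15) and 99.2 ± 11.3 against 66.1 ± 11.8 CPM (0.58, SE 0.16). Among the glycolysis genes, Pgam1, a phosphoglycerate mutase, stood at 26.1 ± 3.39 against 15.6 ± 0.170 CPM (0.75, SE 0.12), and Pfkp, a phosphofructokinase, at 7.85 ± 1.02 against 3.38 ± 0.995 CPM (1.19, SE 0.22). Camera called both lists up (adjusted p = 3.0e-05 and 6.2e-05), and both calls were lost (adjusted p = 0.152 with an estimated correlation for each). Adjusted over the list alone, 5 stress genes and 2 glycolysis genes were higher, and 0 over all genes. From other lists, adjusted over each list alone, Cdkn1a, the cell cycle inhibitor p21, stood at 19.3 ± 5.36 against 8.88 ± 1.19 CPM (1.12, SE 0.22), Igtp, an interferon-induced GTPase, at 24.5 ± 0.797 against 13.7 ± 2.64 CPM (0.83, SE 0.15), and Junb, a transcription factor of the AP-1 family, at 40.1 ± 0.693 against 28.4 ± 0.331 CPM (0.50, SE 0.09). The members given as examples in this and the other comparisons were chosen after their values were seen.

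Of the 76 list tests of GC against vehicle, 29 were called, 16 up and 13 down; the count was 19 without vehicle replicate 1. Of the 29 calls, 16 were lost without vehicle replicate 1 and 15 without GC replicate 2. In stem-like cells, the lists of stem cell maintenance, interferon response, glycolysis and hypoxia, cholesterol synthesis and integrated stress were up, and late granule, S phase, G2 and M phase, heme and lymphoid priming lists were down. Without GC replicate 2, stem cell maintenance pointed down (adjusted p = 0.768), and interferon response (adjusted p = 0.585) and glycolysis (adjusted p = 0.382) were not called. The cholesterol call was lost without vehicle replicate 2 or GC replicate 1 (highest adjusted p = 0.622), and integrated stress without either vehicle replicate, GC replicate 1 or VX replicate 2 (highest adjusted p = 0.981). In cells low in erythroid RNA glycolysis was called (adjusted p = 0.00145), but maintenance, interferon, cholesterol and stress were not (adjusted p = 0.504, 0.645, 0.0673 and 0.111). The late granule call was lost without vehicle replicate 1 (adjusted p = 0.888). The S phase, G2 and M phase and heme lists were instead called up without GC replicate 2 (adjusted p = 0.02, 0.0086 and 4.1e-04), and lost without vehicle replicate 1 (adjusted p = 0.222, 0.389 and 0.0719). They also pointed up in cells low in erythroid RNA (adjusted p = 0.0427, 0.123 and 0.0673). In GMP-like cells, integrated stress and glycolysis were up, and late granule and lymphoid priming lists were down. In monocyte-like cells, primary granule, MHC class II, integrated stress, glycolysis and cholesterol lists were up, and late granule, stem cell maintenance and lymphoid priming lists were down. In erythroid-like cells, heme, integrated stress, glycolysis and cholesterol lists were up, and late granule, lymphoid priming and MHC class II lists were down. Without GC replicate 2, glycolysis pointed down in monocyte-like cells (adjusted p = 0.822) and MHC class II up in erythroid-like cells (adjusted p = 0.867), and without vehicle replicate 1 late granule genes pointed up in erythroid-like cells (adjusted p = 0.206). Over all comparisons, 101 of 304 list tests were called; with an estimated correlation 0 were (smallest adjusted p = 0.128 with an estimated correlation), and 0 members of a called list passed over all genes. Of the 101 calls, 54 were lost without GC replicate 2, 23 without vehicle replicate 1 and 28 without vehicle replicate 2, and 27 pointed the other way in at least 1 alternative. The lists of the NF-kB response, p53 targets, the immediate early response and sex-linked genes were called in no class and no comparison with all libraries. In the alternatives they were called in 3, 3, 17 and 1 of 172 tests each, and the immediate early list in GMP-like cells for GC against vehicle (adjusted p = 0.0511) was called down in 6 of 11 alternatives.

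The second comparison, VXGC against GC, asked what VX added to chemotherapy. In stem-like cells, stem cell maintenance genes stood lower in VXGC, with a median log2 fold change of −0.72 over 19 members, and G2 and M phase genes stood higher, with a median of 0.36 and all 23 members positive. Esam, a surface protein of stem cells, stood at 7.23 ± 1.18 CPM in VXGC and 18.1 ± 9.23 in GC (−1.25, SE 0.35). Gata2, a stem cell transcription factor, stood at 65.2 ± 7.46 and 120.1 ± 44.6 CPM (−0.87, SE 0.26), and Slamf1, the stem cell marker CD150, at 16.8 ± 3.77 and 35.5 ± 16.1 CPM (−1.03, SE 0.32). Without GC replicate 2 the values of Esam and Gata2 were −0.69 and −0.46, and Slamf1 stood at −0.44 in cells low in erythroid RNA. MHC class II genes, which present antigen, stood lower as well (7 members, median −0.54). Camera called the 3 lists (adjusted p = 3.9e-08, 1.1e-08 and 2.9e-04), and each call was lost (adjusted p = 0.713 with an estimated correlation). Adjusted over the list alone, 9 maintenance genes, 0 G2 and M phase genes and 2 MHC class II genes passed. The share of stem-like cells low in erythroid RNA moved with these lists: it was 9.11% and 14.6% in VXGC, and 15.9% and 74.0% in GC. Among stem-like cells low in erythroid RNA alone, the MHC class II list was not called (adjusted p = 0.211), while the maintenance and G2 and M phase lists were (adjusted p = 4.6e-05 and 8.4e-05). With each library left out in turn, the adjusted p of these 2 lists was at most 0.00215 and 0.0142.

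In GMP-like cells, genes of the monocyte and dendritic cell program stood lower in VXGC than in GC, with a median log2 fold change of −0.68 over 10 members. Irf8, the transcription factor that directs progenitors to monocytes and dendritic cells, stood at 51.5 ± 6.43 against 90.7 ± 14.4 CPM (−0.82, SE 0.20). F13a1, a monocyte coagulation factor gene, stood at 39.6 ± 8.01 against 83.5 ± 32.7 CPM (−1.01, SE 0.29), and Ccr2, the receptor that draws monocytes out of the marrow, at 7.74 ± 1.05 against 16.8 ± 1.69 CPM (−1.12, SE 0.36). Over the alternatives the value of Ccr2 ran from −1.47 to −0.37. Camera called the list down (adjusted p = 8.4e-05, adjusted p = 0.284 with an estimated correlation), 4 members passed when adjusted over the list alone, and in cells low in erythroid RNA it was not called (adjusted p = 0.384), with Irf8 and F13a1 at −0.35 and −0.47. Glycolysis genes were called down too (14 members, median −0.46, adjusted p = 1.0e-06, adjusted p = 0.294 with an estimated correlation), whereas after GC alone they had stood higher than in vehicle (median 0.36, adjusted p = 3.7e-06, adjusted p = 0.398 with an estimated correlation; adjusted p = 0.306 without GC replicate 2). The 2 glycolysis results share the GC libraries, so their opposite directions can come from those libraries alone. In monocyte-like cells, primary granule genes stood lower (10 members, median −1.10, adjusted p = 1.0e-06, adjusted p = 0.427 with an estimated correlation), 7 of them when adjusted over the list alone. Mpo stood at 261.8 ± 7.45 against 546.2 ± 233.4 CPM (−1.05, SE 0.25), and Ctsg, the granule protease cathepsin G, at 31.5 ± 7.43 against 134.6 ± 121.8 CPM (−1.97, SE 0.55). GC replicate 2 decides their size: without it the values were −0.55 and −0.58, and over the alternatives they ran down to −1.48 and −2.75. MHC class II genes stood lower there as well (6 members, median −0.59, adjusted p = 2.1e-04, adjusted p = 0.341 with an estimated correlation), with H2-Ab1, a chain of the class II molecule, at 23.3 ± 6.43 against 59.4 ± 8.52 CPM (−1.27, SE 0.28).

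Of the 76 list tests of VXGC against GC, 29 were called, 10 up and 19 down; the count was 16 without GC replicate 2. In stem-like, GMP-like and monocyte-like cells, S phase, G2 and M phase and heme lists were up and the glycolysis list was down. Without GC replicate 2, 18 of the 29 calls were lost. The heme list was then not called in the stem-like, GMP-like or monocyte-like class (adjusted p = 0.688, 0.548 and 0.429) and pointed down in the first and the last, and the S phase list was not called in them either (adjusted p = 0.162, 0.253 and 0.429). In cells low in erythroid RNA, the S phase list was not called in stem-like cells (adjusted p = 0.211) and pointed down in GMP-like cells (adjusted p = 0.412). Down in stem-like cells were also interferon response, stem cell maintenance and MHC class II. The interferon and glycolysis calls there were lost without GC replicate 2 (adjusted p = 0.102 and 0.919) and in cells low in erythroid RNA (adjusted p = 0.211 for each). Down in GMP-like cells were primary granule, granulopoiesis regulators, stem cell maintenance, the monocyte and dendritic cell program and integrated stress. Of these, primary granule pointed up without GC replicate 2 (adjusted p = 0.569), maintenance was lost without GC replicate 1 (adjusted p = 0.0764) and integrated stress without VXGC replicate 1 (adjusted p = 0.0720). In GMP-like cells low in erythroid RNA, only 2 of the 9 lists, heme and glycolysis, were called. There maintenance pointed up (adjusted p = 0.997), primary granule had an adjusted p of 0.927, and granulopoiesis regulators and integrated stress one of 0.384. Down in monocyte-like cells were primary granule, granulopoiesis regulators, lymphoid priming, MHC class II, the monocyte and dendritic cell program, and the inflammasome and IL-1 family (adjusted p = 0.0474, adjusted p = 0.472 with an estimated correlation; lost without GC replicate 2). Granulopoiesis regulators, lymphoid priming, the monocyte and dendritic cell program and glycolysis were lost there too without GC replicate 2 (adjusted p = 0.368, 0.109, 0.429 and 0.523). In erythroid-like cells, lymphoid priming was up, and integrated stress and glycolysis were down. Without GC replicate 2 lymphoid priming pointed down (adjusted p = 0.914), and it was lost without VXGC replicate 1. The other calls were lost without GC replicate 1, GC replicate 2 or VXGC replicate 2 (highest adjusted p = 0.207 and 0.328), and glycolysis also without clusters 2 and 5 (adjusted p = 0.843).

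No single gene passed edgeR's test between VXGC and GC with all libraries, although 3 did in GMP-like cells with the replicate number as a block. The edgeR counts were 0 in the stem-like, GMP-like, monocyte-like and erythroid-like classes, with 1128, 593, 707 and 261 genes at an unadjusted p under 0.05, and DESeq2 called 2, 2, 2 and 0. GC replicates decide these counts: they were 3506, 1293, 899 and 522 without GC replicate 1, and 5, 41, 11 and 188 without GC replicate 2. GMP-like cells made up 3.68% ± 1.48 of VXGC and 6.22% ± 3.51 of GC libraries (log2 ratio −0.76, SE 0.60), monocyte-like cells 1.57% ± 0.379 and 2.55% ± 0.633 (−0.70, SE 0.62), and neutrophil-like cells 0.685% ± 0.145 and 0.356% ± 0.169 (0.94, SE 1.19). Here 0 of 13 classes passed edgeR's test and 0 had an unadjusted p under 0.05 (smallest adjusted p = 0.736).

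The third comparison, VX against vehicle, asked what VX did without chemotherapy. In erythroid-like cells, primary granule genes (11 members, median log2 fold change 0.71) and the monocyte and dendritic cell program (12 members, median 0.82) stood higher after VX. Elane, the neutrophil elastase, stood at 14.6 ± 0.267 CPM after VX and 7.87 ± 1.40 after vehicle (0.90, SE 0.48), and Irf8 at 11.1 and 16.5 CPM in the VX libraries and 8.26 and 8.54 in the vehicle libraries (0.69, SE 0.31). Camera called both lists up (adjusted p = 2.0e-06 and 1.5e-06), and both calls were lost (adjusted p = 0.564 with an estimated correlation for each); adjusted over the list alone, 0 members passed. In stem-like cells, late granule genes stood higher after VX (11 members, median 0.64, adjusted p = 4.2e-07, adjusted p = 0.728 with an estimated correlation). That list pointed the other way without vehicle replicate 2 (adjusted p = 0.898), and was not called in cells low in erythroid RNA (adjusted p = 0.472). In GMP-like cells Chil3 stood at 59.0 ± 0.916 and 24.5 ± 14.6 CPM (1.26, SE 0.39), but its value was 0.091 in cells low in erythroid RNA and 2.06 without vehicle replicate 1. Neutrophil-like cells made up 5.53% and 1.77% of the VX libraries, and 9.22% and 0.448% of the vehicle libraries.

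Of the 76 list tests of VX against vehicle, 17 were called, 15 up and 2 down; the count was 7 without vehicle replicate 2, where 14 of the 17 calls were lost. In stem-like cells, late granule, monocyte and dendritic cell, and cholesterol lists were up and stem cell maintenance was down. In GMP-like cells, late granule, S phase, G2 and M phase, lymphoid priming, and monocyte and dendritic cell lists were up and primary granule was down. In cells low in erythroid RNA, 0 of these 4 stem-like and 0 of these 6 GMP-like calls remained (adjusted p of at least 0.472 and 0.0524). Without vehicle replicate 2, the late granule list in GMP-like cells pointed down (adjusted p = 0.968). In erythroid-like cells, the 7 lists called were up: primary granule, late granule, granulopoiesis regulators, the inflammasome and IL-1 family, stem cell maintenance, lymphoid priming, and the monocyte and dendritic cell program. These lists hold markers of several other cell types, which thus moved together in the erythroid-like class; RNA or cells of other types were not tested as their source. Without vehicle replicate 2, the late granule list there was called down (adjusted p = 0.00525). No list was called in monocyte-like cells. The edgeR gene counts were 0 in the stem-like, GMP-like, monocyte-like and erythroid-like classes, with 105, 188, 100 and 173 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each. They were 1, 6, 1 and 1 without GC replicate 1, 2, 6, 1 and 1 without GC replicate 2, and 5 in the monocyte-like class without vehicle replicate 1. Of 13 classes, 0 differed in share in edgeR's test, with 0 at an unadjusted p under 0.05 (smallest adjusted p = 0.866, with the neutrophil-like log2 ratio at −0.41, SE 1.16).

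The interaction asked whether VX acted differently with and without GC. In GMP-like cells, the monocyte and dendritic cell program stood lower in the interaction, with a median log2 difference of −0.87 over 10 members (adjusted p = 3.9e-07, adjusted p = 0.356 with an estimated correlation), 1 of them when adjusted over the list alone. In stem-like cells, G2 and M phase genes stood higher (23 members, median 0.31, adjusted p = 1.5e-05, adjusted p = 0.624 with an estimated correlation). That call was lost without GC replicate 2 (adjusted p = 0.483) and in cells low in erythroid RNA (adjusted p = 0.119). Of 76 list tests, 26 were called, 8 up and 18 down, and 14 without GC replicate 2, where 20 of the 26 calls were lost. The edgeR gene counts were 0 in the stem-like, GMP-like, monocyte-like and erythroid-like classes, with 424, 227, 227 and 224 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each. They were 1465, 315, 190 and 42 without GC replicate 1, 20, 51, 18 and 303 without GC replicate 2, and 4 in the monocyte-like class without vehicle replicate 1. Of 13 classes, 0 passed in share, with 0 at an unadjusted p under 0.05 (smallest adjusted p = 0.848, with the neutrophil-like value at 1.35, SE 1.66).

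Casp1, the target of the inhibitor in the protocol, and the genes of its substrates did not pass with all libraries in the classes where they were tested. All 4 genes were tested in stem-like and erythroid-like cells, Casp1 and Gsdmd alone in GMP-like cells and Gsdmd alone in monocyte-like cells. Casp1 (ENSMUSG00000025888, chromosome 9, 5298517 to 5307265, plus strand) stood in GMP-like cells at 16.96 ± 5.36 CPM in vehicle, 20.7 ± 9.59 in GC, 15.5 ± 3.29 in VXGC and 10.2 ± 0.131 in VX. The log2 fold change was 0.19 (SE 0.35) for GC against vehicle and −0.72 (SE 0.43) for VX against vehicle. The first ran from −0.28 to 0.71 over the alternatives and turned negative without vehicle replicate 1 or GC replicate 2, and the second ran from −1.02 to −0.30. In stem-like cells it stood at 4.11 ± 0.468 CPM in vehicle and 7.91 ± 5.06 in GC (0.81, SE 0.46, adjusted p = 0.963), with a range from 0.098 without GC replicate 2 to 1.70 with the strict filter. Without GC replicate 1 it was 1.48 (Casp1, GC vs vehicle: stem and multipotent progenitor). For VX against vehicle, Casp1 in stem-like cells went the other way than in GMP-like cells, at 0.79. That value ran from 0.46 to 1.36 and was positive in 17 of 17 alternatives. For VXGC against GC without GC replicate 1, Casp1 and Il18 in stem-like cells were at −1.06 (Casp1, VXGC vs GC: stem and multipotent progenitor) and −1.18 (Il18, VXGC vs GC: stem and multipotent progenitor). The GC group is then GC replicate 2 alone, which stood apart in erythroid transcripts, so these values rest on that 1 library. Gsdmd, the pore-forming substrate gasdermin D (ENSMUSG00000022575, chromosome 15, 75862327 to 75867408, plus strand), stood at 17.2 ± 4.22 CPM in vehicle and at 18.3 and 13.7 CPM in the GC libraries in GMP-like cells, and at 11.7 ± 0.747 and 13.7 ± 1.78 CPM in monocyte-like cells. Il18, a cytokine that Casp1 activates (ENSMUSG00000039217, chromosome 9, 50554827 to 50581840, plus strand), stood at 7.87 ± 1.42 CPM in vehicle and 8.95 ± 4.95 in GC in stem-like cells. Il1b, the other such cytokine (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, minus strand), stood at 1.49 ± 1.54 CPM in vehicle and 0.593 ± 0.388 in GC in stem-like cells, a level close to the 1.08 CPM of erythroid-like cells.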

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

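No test was run on the share below, and the alternative that leaves its cells out was chosen after its size was seen. In VX replicate 2, 41.3% of kept cells fell into cluster 8, which carried no cell type name; the highest vehicle library had 2.55%, and the other libraries had 0.0165% to 2.55%. It drew attention because these cells lie outside the classes compared and far exceed their level in the control samples. The leading genes of the cluster were mixed: Sox4, Satb1, Tox and Dntt of lymphoid cells stood beside Cd34 of progenitors and beside Rsad2 and Xpo7, which also led erythroid cluster 6. Of the erythroid markers, 10 stood above every named cluster outside the erythroid-like class. With the second clustering, its counterpart held 41.6% of that library and was led by genes of several cell types, among them Iglc2 of B cells, Retnlg of neutrophils, Hba-a2 of red cells and Cpa3 of mast cells. VX replicate 2 also had the lowest median depth before filtering, 1005 UMIs per barcode.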

How the results depend on the processing

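The alternatives that keep barcodes from 500 UMIs, that take only cells low in erythroid RNA or that leave out cluster 8 or clusters 2 and 5, and the gene tests of 4 libraries given a drug against 4 not given it, were chosen after the data were seen. The strict filter, doublets kept and the second clustering were not planned for the permutation tests of drug effects. Of 384 alternative values for class shares, 344 kept their direction and side of the threshold or their count. So did 69 of 77 values of the drug effects on shares, 275 of 331 values of single lists and 3235 of 3402 values of single genes. The list values cover only 28 list tests picked for the report out of 304, so they do not speak for all lists. With all libraries no share or drug effect passed, and of the single genes only the 4 erythroid ones did. For shares and genes, keeping the side of the threshold thus mostly meant staying uncalled. Within 1.5 times the reported count stayed 190 of 264 gene counts, 36 of 44 list counts, and only 4 of 36 gene counts for 4 libraries against 4. RLE in place of TMM shifted the median of all genes by at most 0.0074 on the log2 scale. Of the 4 erythroid genes of GC against vehicle, each kept its sign in 17 of 17 alternatives, and Cpd was called in 10, Tjp1 in 12, Prss50 in 8 and Gm11837 in 10, with a highest adjusted p of 0.366. The monocyte-like class had a depth of as few as 183 cells in a library, and simulated 2-fold changes were recovered there at 11% to 53%. Where no cause is given, the cause was not tested.

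Gene counts moved as follows. With DESeq2, GC against vehicle gave 97 genes in erythroid-like and 3 in stem-like cells, and VXGC against GC gave 2 each in stem-like, GMP-like and monocyte-like cells. Without the filter on low counts, which tests more genes, the stem-like, GMP-like, monocyte-like and erythroid-like counts were 123, 33, 26 and 409 for GC against vehicle, 258, 87, 54 and 31 for VXGC against GC, 7, 8, 6 and 32 for VX against vehicle, and 11, 5, 4 and 27 for the interaction. With only the 2 groups compared, which leaves fewer libraries to estimate the spread, GC against vehicle gave 0 genes in erythroid-like cells, and VX against vehicle gave 2, 16 and 1 in stem-like, GMP-like and monocyte-like cells. The strict cell filter gave 22 genes in erythroid-like cells for GC against vehicle. With doublets kept, that comparison gave 6, 1 and 2 in stem-like, GMP-like and monocyte-like cells. In cells low in erythroid RNA it gave 7 in stem-like cells. In the neutrophil-like class, which could be tested only where every library held enough cells, keeping doublets gave 3 genes for GC against vehicle and 1 for VX against vehicle, and barcodes from 500 UMIs gave 1 for GC against vehicle.

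With each library left out in turn, the counts for GC against vehicle ran from 0 to 1637 in erythroid-like, 0 to 2126 in stem-like, 0 to 738 in GMP-like and 0 to 337 in monocyte-like cells. For VXGC against GC they ran from 0 to 522, 0 to 3506, 0 to 1293 and 0 to 899 in the same order, each highest without GC replicate 1. For VX against vehicle they ran from 0 to 1, 0 to 2, 0 to 6 and 0 to 5, and for the interaction from 0 to 303, 0 to 1465, 0 to 315 and 0 to 190.

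The labels do not say whether equal replicate numbers share a day or batch, so the block is only an alternative. Over 24 pairs of groups, the correlation of same-numbered libraries' deviations ran from −0.303 to 0.478, and 11 were over 0.1, among them vehicle with GC in each of 4 classes (0.478, 0.395, 0.177 and 0.130). With the replicate number as a block, GC against vehicle gave 7 genes in erythroid-like and 2 in monocyte-like cells, VXGC against GC gave 3 in GMP-like cells, and 1 class (B lineage, log2 ratio −2.98, adjusted p = 0.0402) passed in share for GC against vehicle. In the block fit the stem-like ratio was −0.0095 for GC against vehicle, and the neutrophil-like ratio 0.10 for VX against vehicle. List counts with the block were 30, 30, 17 and 30. The block changed no other count of calls by more than 1.5 times.

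The log2 ratios of class shares below turned sign against the reported value, and none of them passed its test. With TMM over classes, the erythroid-like and stem-like values were 0.065 and 0.36 for VX against vehicle, −0.25 and −0.15 for VXGC against GC, and −0.31 and −0.51 for the interaction. With the strict filter, they were −0.21 for monocyte-like and −0.16 for stem-like cells in GC against vehicle, and 0.011, 0.015 and 0.075 for erythroid-like, monocyte-like and stem-like cells in VX against vehicle. The drug effects there were −0.12 for GC on stem-like and 0.069 for VX on erythroid-like cells. With barcodes from 500 UMIs, the stem-like ratio for GC against vehicle was −0.048, and the drug effects were 0.14 for GC on monocyte-like and −3.4e-05 for VX on stem-like cells. With the second clustering, the stem-like values were −0.13 for VXGC against GC and −0.16 for VX as a drug effect. Without cluster 8, the erythroid-like and stem-like values for VX against vehicle were 0.0099 and 0.28, the stem-like interaction was −0.15, and the drug effects were −0.078 for GC on stem-like and 0.094 for VX on erythroid-like cells. Without clusters 2 and 5, the erythroid-like value was −0.068 for VXGC against GC. On a linear scale, the VX effect on the neutrophil-like share was −0.43 percentage points. Other drug effects kept their sign but shrank: GC on erythroid-like cells to 0.35 (strict filter), GC on GMP-like cells to 0.27 (without cluster 8), VX on GMP-like cells to −0.14 (second clustering) and VX on monocyte-like cells to −0.13 (strict filter).

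With each library left out in turn, log2 ratios for GC against vehicle ran from −0.052 to 1.17 in GMP-like, −0.46 to 0.41 in stem-like, −0.34 to 0.51 in monocyte-like and −4.69 to −0.33 in neutrophil-like cells, and 0 to 3 classes passed. For VXGC against GC they ran from −0.18 to 0.48 in erythroid-like and −0.24 to 0.62 in stem-like cells. For VX against vehicle they ran from −0.70 to 0.0026 in erythroid-like, −1.20 to 0.28 in monocyte-like, −1.45 to 3.03 in neutrophil-like and −0.30 to 0.11 in stem-like cells. For the interaction they ran from −0.81 to 0.41 in GMP-like, −0.16 to 0.70 in stem-like, −0.99 to 0.50 in monocyte-like and −2.09 to 2.39 in neutrophil-like cells.

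Of the lists, 0 were called in any comparison with an estimated correlation. Leaving out each library gave 19 to 36 calls for GC against vehicle, 16 to 32 for VXGC against GC, 7 to 23 for VX against vehicle and 14 to 29 for the interaction. Leaving that alternative aside, 74 of the 101 calls kept their direction in all alternatives run for lists and 12 were called in all of them. The late granule list in monocyte-like cells for GC against vehicle ran from an adjusted p of 5.8e-33 without vehicle replicate 2 to 0.142 in the other direction without vehicle replicate 1. With each library left out, the log2 fold change of Ngp there ran from −4.36 to 0.71, and that of Camp (Camp, GC vs vehicle: monocyte lineage) from −3.62 to 0.47; with the strict filter Camp stood at −5.40. The late granule list in stem-like cells for VX against vehicle ran from 3.5e-23 without vehicle replicate 1 to 0.898 in the other direction without vehicle replicate 2, and in erythroid-like cells from 2.7e-42 without vehicle replicate 1 to 0.00525 in the other direction without vehicle replicate 2. In stem-like cells for GC against vehicle, with each library left out, the S phase list ran from an adjusted p of 1.2e-07 to 0.222, G2 and M phase from 2.6e-07 to 0.389 and heme from 2.0e-10 to 0.0719, each turning up without GC replicate 2. In cells low in erythroid RNA they turned up as well (0.0427, 0.123 and 0.0673). For VXGC against GC, the heme list ran from 1.2e-10 to 0.688 in stem-like and from 3.8e-12 to 0.429 in monocyte-like cells, turning down without GC replicate 2, and in cells low in erythroid RNA the S phase list turned down in GMP-like cells (0.412). The 2 vehicle libraries differ strongly in neutrophil-like cells, at 9.22% and 0.448%.

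The counts of genes that differ in the 4 libraries given GC moved too. In stem-like cells the count was 0 with the strict filter, 34 with doublets kept, 42 in cells low in erythroid RNA, 5 with barcodes from 500 UMIs and 0 to 70 with each library left out. In erythroid-like cells it was 80, 16, 20 and 153 with the strict filter, doublets kept, barcodes from 500 UMIs and without clusters 2 and 5, and 0 to 106 with each library left out. In early lymphoid-like cells it was 119 with doublets kept, 80 in cells low in erythroid RNA, 37 with barcodes from 500 UMIs and 5 to 297 with each library left out. No alternatives are given for the counts for VX.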

Other observations

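All tests below were chosen after the results they concern were seen, and so were the genes described. Early lymphoid-like cells, a class outside the comparisons above, held lower levels of 8 genes, Ebf1 and Pax5 among them, in the libraries given GC. Comparing the 4 libraries given GC (alone or with VX) with the 4 not given it, edgeR called 8 genes of 11666, all lower with GC. Ebf1, a transcription factor that sets up the B cell program, fell from 164.1 ± 25.2 to 47.6 ± 14.1 CPM (SD, n = 4 per group; log2 fold change −1.81, SE 0.19, adjusted p = 0.00349). Pax5, which fixes B cell identity, fell from 14.2 ± 3.34 to 2.91 ± 1.17 CPM (−2.34, SE 0.27, adjusted p = 0.00488). Agbl4, a carboxypeptidase gene, fell from 139.7 ± 13.8 to 45.6 ± 14.5 CPM (−1.63), and Auts2, Col19a1 and Arpp21 fell by 0.73, 1.16 and 0.93 on the log2 scale. The other 2 genes called are among the markers that name the class. The count was 5 without vehicle replicate 1, GC replicate 1, VXGC replicate 2 or VX replicate 2, 16 without vehicle replicate 2, 297 without GC replicate 2 and 14 without VXGC replicate 1. B-lineage-like cells made up 0.820% ± 0.488 of the libraries given GC and 3.51% ± 2.25 of the others (difference of mean log2 shares −2.32, exact permutation p = 0.0286, the smallest that 70 arrangements can give, and adjusted p = 0.495 over 13 classes and 2 drugs).

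In stem-like cells the same comparison called 1 gene, Satb1 (ENSMUSG00000023927, chromosome 17, 51736187 to 51833290, minus strand), which fell from 63.5 ± 2.55 to 34.7 ± 4.26 CPM (−0.86, SE 0.10, adjusted p = 0.0460). It called 0 genes without any 1 of vehicle replicate 1, GC replicate 1, VXGC replicate 1, VXGC replicate 2, VX replicate 1 and VX replicate 2, 8 without vehicle replicate 2 and 70 without GC replicate 2. In erythroid-like cells it called 44 genes, 16 higher and 28 lower with GC. Podxl, the surface sialomucin podocalyxin, rose from 6.00 ± 3.32 to 43.1 ± 25.7 CPM (2.79), Tjp1 from 2.47 ± 0.306 to 15.9 ± 5.37 CPM (2.68) and Igtp from 13.6 ± 1.69 to 22.03 ± 3.21 CPM (0.70). Bach2, a transcriptional repressor, fell from 17.5 to 22.9 CPM in the libraries without GC to 5.68 to 11.4 CPM in those with it (−1.10). Bach2 was also a leading gene of the B lineage cluster, whose share was lower in libraries given GC (0.820% against 3.51%). RNA or cells of the B lineage were not tested as its source here. Spon2, a secreted matrix protein, fell from 12.8 ± 2.11 to 4.41 ± 1.48 CPM (−1.55). The erythroid count was 0 without vehicle replicate 1, VX replicate 1 or VX replicate 2, 20 without vehicle replicate 2, 106 without GC replicate 2 and 14 without VXGC replicate 2, and it was 153 without clusters 2 and 5. Of the 35 ways to split the 8 libraries into 4 and 4, only 1, the real one, reached 1 gene in stem-like or 44 in erythroid-like cells, and the highest other split gave 0 in each. That is the smallest share 35 splits can give, in tests chosen after the data were seen, so it argues against chance without excluding it.

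For the 4 libraries given VX against the 4 not given it, edgeR called 0 genes in stem-like, erythroid-like and early lymphoid-like cells, with 525, 169 and 502 at an unadjusted p under 0.05. A count of 0 is reached by all 35 splits whatever the data hold, so the splits say nothing about chance here. The highest other splits, which are those by GC, gave 1, 44 and 8 genes.

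The 8 genes lower in early lymphoid-like cells given GC were weighed against chance and stray RNA of other cells. Only 1 of 35 splits gave 8 genes and the highest other gave 0, the smallest share these splits can give, which argues against chance. Taking off in each library the highest Ebf1 level of 5 classes that should lack it left the log2 ratio at −1.74, from −1.84. For Ebf1 this argues against free RNA from B lineage cells as the whole source. The other genes were not put to this check, and B lineage cells counted within the class were not tested as a source. In cells low in erythroid RNA the median of the 8 genes was −1.62, from −1.46 over all cells, and all 8 were still called, which argues against erythroid transcripts in these cells as the whole cause. An effect of GC within these cells and a changed mix of them were not told apart. In the second clustering, the cluster named early lymphoid, led by Dntt, Arpp21 and Agbl4, held 11.8% to 20.5% of the class in libraries given GC. It held 26.7% to 30.9% in the others, but genes that lead it are among the 8. Most of the class fell into clusters named otherwise there. A cluster named GMP-like held 51.2% and 9.59% of it in GC replicates 1 and 2, and 55.7% and 52.8% in VXGC replicates 1 and 2. It held 25.3% to 34.2% in the libraries without GC. Clusters named stem-like and monocyte-like held 38.0% and 34.8% of the class in GC replicate 2.

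The lower late granule genes in GMP-like cells of GC against vehicle followed the neutrophil-like share, so stray neutrophil RNA was a candidate source. After the highest level of these 6 genes in 5 classes that should lack them was taken off in each library, the log2 ratio was −1.53, from −1.61, which argues against free RNA as the whole source. Ltf and Retnlg, abundant in mature neutrophils, reached a median of 6.66% of the level that the S100a8 of the class would need if it came from neutrophil-like cells. The share ran from 0% to 23.8% per library, highest in vehicle replicate 1. Cells with the make-up of the neutrophil-like class are thus not the whole source, but a part stays open. Immature neutrophils low in Ltf and Retnlg and counted among the progenitors would give the same low share, so the check cannot exclude them. An effect of GC stays open: libraries with and without GC differed by −1.72 in mean log2 CPM (exact permutation p = 0.0571).

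The lower stem cell maintenance genes of VXGC against GC could come from GC replicate 2 alone. They could also come from free erythroid transcripts in the cells of the other libraries. The median log2 fold change over all cells and libraries was −0.72. It was −0.38 (SE 0.09) in cells low in erythroid RNA and −0.32 (SE 0.08) without GC replicate 2. These errors come from the spread over the genes of the list and do not measure the spread between libraries. Each value lies within its error of 50 percent of the full value. Neither a part played by these transcripts nor one played by that library can be told apart from an effect of VX, which stays untested.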
